A study of Mus musculus with 6 samples.

How the data were processed

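The data are from mouse expression arrays, per the labels, hybridised with biotin-labelled cRNA made from total RNA of the uterine horns of ovariectomized GATA2 f/f females: 3 arrays after oil and 3 after P4. The deposited values are linear intensities, 1 per probe set and array; how they were summarised and scaled is not given in the sources used here. The files hold 45101 probe sets, of which 64 are controls. The number of arrays limits the precision of every value. Nothing in the labels says that the arrays came from separate animals, so p-values measure the spread between these samples, which may be technical. No 2 arrays shared more than 7 identical values, and correlations of log2 values ran from 0.967 to 0.994.

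Intensities were turned into log2(intensity + 16), with no further normalization, since the medians of the arrays differed by 0.059 log2, under the limit of 0.5 set in advance for quantile normalization. Fold changes are on that scale, which understates changes of dim genes. Gene names came from the platform annotation: 34945 probe sets had 1 gene symbol, 932 had several and 9160 are unnamed here. Of the first, 34741 matched by gene ID to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Probe sets with several names or none were left out of the gene tests. For each gene the probe set with the highest mean over all arrays was used, which gave 18193 genes. A different probe set of the same gene is named where it had the opposite sign at an unadjusted limma p under 0.05. Opposite signs at a higher p are not named.

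P4 was compared with oil by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) over all 6 arrays without covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 33 gene lists (progesterone response, uterine signalling, cell types, stress) held 872 genes, 809 of them measured; they were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 33 lists, with an estimated correlation and fry beside it. With an estimated correlation 0 of the 5 camera calls held. An unadjusted camera p under 0.05 was found for 9 of the 33 lists with the preset value and 3 with the estimated one. Fry called 6 by its directional test, which is meant by fry below unless its mixed test is named. The mixed test asks whether members change in either direction. Neither fry test compares members with other genes. The list members, the tests, the named-gene rule and most alternatives were fixed before the data were examined. The rule names the 12 largest increases and decreases among called genes without overlap between groups, up to 4 called members of each list by size, 11 genes chosen in advance and, for lists with few calls, members of high level as values only. It gave 130 genes. Figures were drawn with matplotlib 3.10.9.

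The replicate numbers 1 to 3 occur in both groups. Deviations from the group means correlated at 0.53, 0.13 and 0.64 between arrays of the same number, each above the limit of 0.1 set in advance, so the numbers were taken to pair the arrays. This rests on the data, as the labels share only the number, and oil replicate 2 correlated more with P4 replicate 1 (0.29) than with its own number. A fit with the replicate number as a block is given where it changes a call or moves a count by more than 1.5 times.

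The gene test was tested on simulated data with the real means and spreads of 18193 genes, 200 of them changed, over 20 runs. It recovered 36.3% of genes changed by 0.5 log2, 83.2% of those changed by 1, 97.6% by 2 and 98.8% by 3. Of the calls 5.11% were false, and 100% of true calls had the right sign. The real comparison called 2368 genes. The adjustment depends on how many genes change, so the recovered shares may not carry over to it. A list shifted by 0.5 log2 was found in 20 of 20 runs, and 1 unshifted list was called over all runs; simulated genes varied independently, so this leaves open the false list calls under the correlation of real arrays, where other splits called up to 17 lists.

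Alternatives were quantile normalization, median centring, the mean of a gene's probe sets, leaving out probe sets open to cross-hybridisation, leaving out the dimmest 30% or 50% of genes, pseudocounts of 1 and 50, other moderation settings, array weights, all probe sets, other thresholds, the replicate block and each array left out. Chosen after seeing the data were scaling to the hybridisation controls, the 3' to 5' ratio of control transcripts or the mean of the granulocyte list as a covariate, and leaving out both arrays of 1 number.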

Results

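Gene expression was measured on 6 arrays of uterine horns from ovariectomized mice that carried the GATA2 f/f genotype, which by convention denotes a floxed allele on both chromosomes. The labels name no recombinase. One group of 3 received oil, a usual carrier of steroid hormones, and the other group of 3 received P4, the standard abbreviation of progesterone. Ovariectomy removes the main source of ovarian steroids. The median probe set intensity ran from 117 to 123 over the 6 arrays, so no array was markedly dimmer than the others. The title of the series concerns binding of the progesterone receptor and GATA2 in the mouse uterus, and the comparison of P4 with oil asks which uterine transcripts differ after the hormone. The labels give no dose and no time after treatment. Intensities are given as the mean ± SD of 3 arrays, and fold changes as the log2 difference ± SE of P4 against oil.

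The largest increase after P4 was that of Slc6a14, an amino acid transporter, with an intensity of 49.5 ± 47.1 after oil and 1039 ± 386 after P4, a log2 fold change of 4.18 ± 0.45. Pate4 rose by 3.55 ± 0.14 and Npl, a lyase of sialic acid breakdown, by 3.46 ± 0.29. Lrp2, the endocytic receptor megalin, went from 95.9 ± 7.22 to 1171 ± 386 (3.36 ± 0.20). Il13ra2, a decoy receptor for interleukin 13, rose from 56.6 ± 12.5 to 578 ± 37.6. Cyp26a1, which breaks down retinoic acid, rose by 2.96 ± 0.31, and Hsd11b2, which inactivates glucocorticoids, by 2.94 ± 0.16. The other genes among the 12 largest increases were Acot7 (2.95 ± 0.25), Map7d2 (2.94 ± 0.21), Mthfd2 (2.67 ± 0.20), Sgk1 (2.57 ± 0.14) and Fkbp5 (2.55 ± 0.20). Their limma adjusted p ran from 0.000123 for Pate4 to 0.00169 for Slc6a14.

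The largest decrease was that of Gabrp, a subunit of the GABA-A receptor, from 1106 ± 413 to 166 ± 126 (-2.77 ± 0.45). Cdkl1 fell to 57.6 ± 16.5 from 370 ± 83.2 (-2.40 ± 0.21). Pik3ip1, an inhibitor of phosphoinositide 3-kinase, had a log2 fold change of -1.83 ± 0.15. Wnt7a, a Wnt ligand of the uterine epithelium, had one of -1.63 ± 0.14. The other genes among the 12 largest decreases were Speer4cos (-1.91 ± 0.24), the retinoid transporter Abca4 (-1.87 ± 0.18), Dclk3 (-1.76 ± 0.17), Klhl14 (-1.69 ± 0.09), Acpp (-1.68 ± 0.20), Ctnnd2 (-1.63 ± 0.22), Capsl (-1.63 ± 0.25) and the peptide transporter Slc15a2 (-1.55 ± 0.24). Their adjusted p ran from 0.000421 for Klhl14 to 0.00754 for Gabrp. All 24 of these largest changes kept an adjusted p under 0.05 with any 1 array left out. Leaving out both arrays numbered 2, a choice made after seeing the data, ended the calls of Slc6a14 (adjusted p 0.0621), Cyp26a1 (0.0573) and Gabrp (0.118). It also ended those of Speer4cos, Acpp, Ctnnd2, Capsl and Slc15a2 (up to 0.121).

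**Figure D1:**
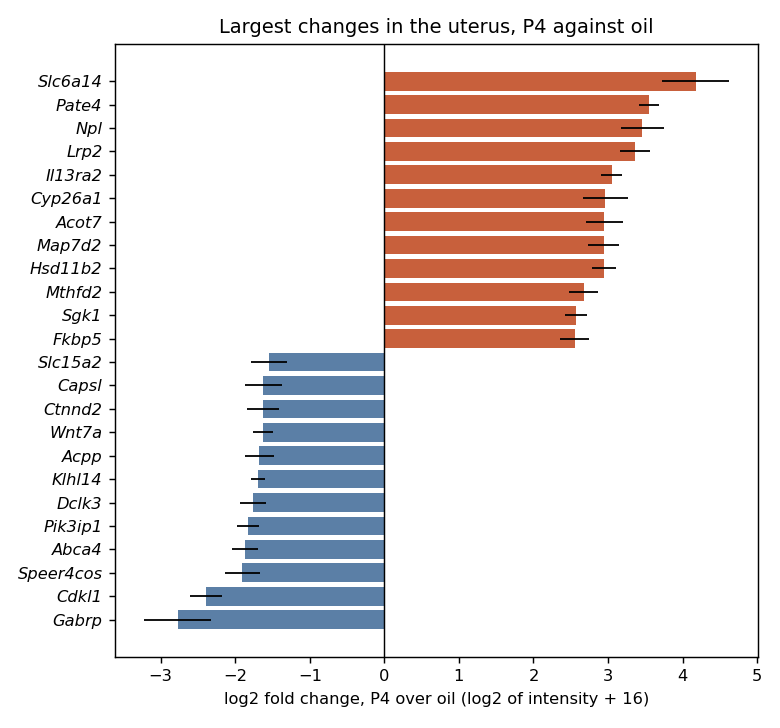
Log2 fold change of P4 over oil (horizontal axis, log2 of intensity + 16) for the 12 largest increases and 12 largest decreases. Bars are fitted differences of 3 against 3 arrays and lines are ± 1 SE; increases reach 4.18 (Slc6a14) and decreases reach -2.77 (Gabrp).

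Of 18193 genes, 2368 changed at a limma adjusted p under 0.05, 1106 higher and 1262 lower after P4 (46.7% higher). At least 2-fold changes were 180 higher and 104 lower, and at least 4-fold changes were 27 higher and 2 lower, the latter being Gabrp and Cdkl1. In all 2368 the 3 P4 arrays lay on 1 side of the 3 oil arrays. Among all genes 31.8% had no overlap, where chance gives 10% for 6 exchangeable arrays. Arrays paired by number would not be exchangeable, so the 10% is only a rough guide. With the replicate number as a block, 3801 genes passed (1690 higher, 2111 lower), all 2368 among them in the same direction. The count depends on single arrays: it was 990 without oil replicate 2, 1175 without oil replicate 1 and 1405 without P4 replicate 2, and 896 genes (446 higher, 450 lower) were called in all 6 such fits. Leaving out both arrays numbered 2, a choice made after seeing the data, left 171 calls and ended 73 of the 110 calls among the genes named by the rule. Hybridisation control probe sets were 0.127 log2 lower on the P4 arrays (exact two-sided permutation p 0.1, the smallest that 3 against 3 arrays can give), and scaling to them moved the median of all genes by 0.13 log2 and gave 1927 higher and 624 lower (75.5% higher).

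Among the genes chosen in advance, Gata2 was higher and the progesterone receptor lower after P4. Gata2 transcript rose from 3699 ± 227 to 6271 ± 964, a log2 fold change of 0.75 ± 0.11 (limma adjusted p 0.00541). Transcript of the progesterone receptor, Pgr, was lower after P4, at 2098 ± 112 against 3815 ± 327 (-0.86 ± 0.09, adjusted p 0.00124). Ihh, the hedgehog ligand of the uterine epithelium, rose from 196 ± 67.6 to 674 ± 84.7 (1.75 ± 0.22, adjusted p 0.00311), while Ptch1, the hedgehog receptor, had a log2 difference of -0.21 ± 0.17 that did not pass (adjusted p 0.504). Nr2f2, an orphan nuclear receptor of the stroma, had a difference of 0.00 ± 0.07 (adjusted p 0.981). Hand2, a stromal transcription factor, rose by 0.50 ± 0.10 (adjusted p 0.0165) and Sox17 by 0.58 ± 0.12 (adjusted p 0.0173). Esr1, the estrogen receptor, had a log2 fold change of -0.36 ± 0.07 (adjusted p 0.0153). Of these calls 3 rest on single arrays: Sox17 lost its call without any 1 oil array (adjusted p up to 0.0677), Hand2 without oil replicate 2 or 3 (up to 0.0707) and Esr1 without oil replicate 1 or 2 (up to 0.0743). Esr1 also missed the threshold with the mean of all its probe sets (0.12) and with scaling to the hybridisation controls (0.0624), and Sox17 with quantile normalization (0.052). Gata2 (limma adjusted p 0.0788) and Pgr (0.0573) lost their calls with both arrays numbered 2 left out, a choice made after seeing the data. So did Hand2 (0.0903), Sox17 (0.134) and Esr1 (0.157). Of the 11 genes chosen in advance, 1 is not analysed here.

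**Figure D2:**
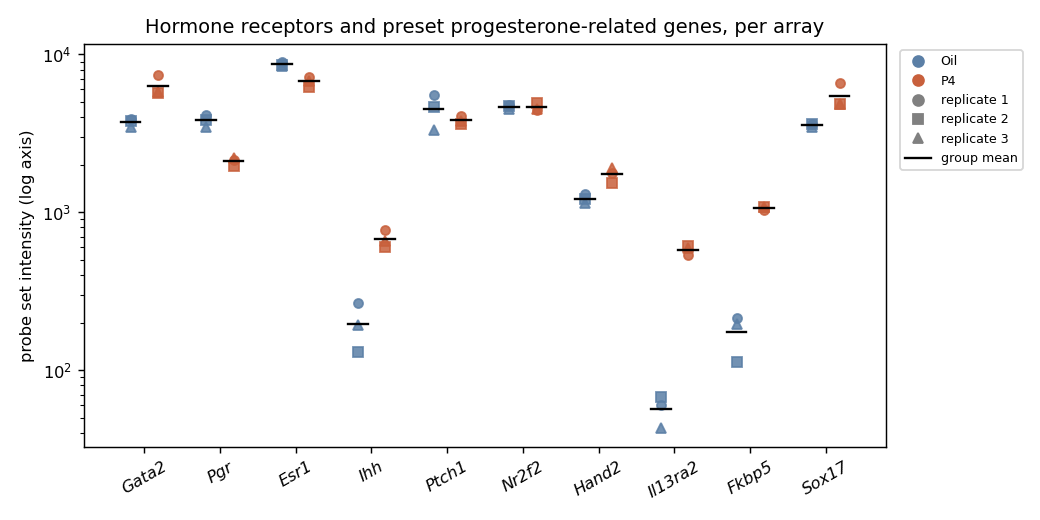
Probe set intensity per array (vertical log axis) for 10 genes chosen in advance; blue points are oil arrays, orange points P4 arrays, symbols the replicate numbers and black lines the means of 3 arrays. Gata2 has means of 3699 after oil and 6271 after P4, and Pgr of 3815 and 2098.

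Of 38 measured known progesterone targets of the mouse uterus 16 rose after P4 and 6 fell (17 and 7 adjusted over the list alone). Besides the genes above, Zbtb16, a transcriptional repressor, rose by 2.01 ± 0.26, Hdc, which makes histamine, by 1.91 ± 0.32 and Errfi1, a feedback inhibitor of the EGF receptor, by 1.27 ± 0.16. Fst, the activin antagonist follistatin, rose by 2.03 ± 0.42, a call lost without oil replicate 1, oil replicate 2 or P4 replicate 2 (adjusted p up to 0.0783) and with robust moderation (0.0793). The list's name gives no direction of change. Among the members that fell, Lifr, the receptor of leukemia inhibitory factor, had the largest decrease (-1.09 ± 0.16). It was named after its value was seen. Of 29 genes shared with the glucocorticoid response 9 rose and 2 fell (11 and 3 adjusted over the list alone). The metallothionein Mt1 rose by 1.45 ± 0.16, a call lost when probe sets open to cross-hybridisation were left out (adjusted p 0.059). The decreases were Pdk4, an inhibitor of pyruvate oxidation (-1.39 ± 0.09), and the repressor Bcl6 (-0.62 ± 0.12; lost without 1 array, adjusted p up to 0.0507), both named after their values were seen. Camera with a preset inter-gene correlation gave an adjusted p of 0.00208 for the first list and 0.00202 for the second. For both, adjusted p = 0.45 with an estimated correlation, and the first had 0.0568 with scaling to the hybridisation controls. Fry gave an adjusted p of 0.00936 for the first list and 0.0108 for the second.

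Many genes for making ribosomes and for folding proteins in the endoplasmic reticulum rose after P4. In the ribosome biogenesis list 22 of 31 measured genes rose and 0 fell (29 and 0 adjusted over the list alone, and 29 and 0 by limma at an unadjusted p under 0.05), with a mean log2 difference of 0.60. Rrp12 rose from 91.4 ± 8.53 to 273 ± 50.1 (1.42 ± 0.14), Rrs1 by 1.18 ± 0.11, the helicase Ddx21 by 1.12 ± 0.09 and the small nucleolar RNA protein Nop56 by 0.89 ± 0.08. In the unfolded protein response list 14 of 25 rose and 0 fell (17 and 0 adjusted over the list alone, and 18 and 0 by limma at an unadjusted p under 0.05), with a mean of 0.50. Hspa5, the chaperone BiP, rose from 3842 ± 303 to 8176 ± 104 (1.09 ± 0.07), Manf by 1.32 ± 0.14 and the asparagine synthetase Asns by 1.41 ± 0.11. Camera gave adjusted p values of 1.28e-20 for ribosome biogenesis and 3.27e-11 for the unfolded protein response. For both, adjusted p = 0.45 with an estimated correlation. Fry gave an adjusted p of 0.00735 for ribosome biogenesis and 0.00818 for the unfolded protein response. Without oil replicate 1 or oil replicate 2 the unfolded protein response list had 9 increases.

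**Figure D3:**
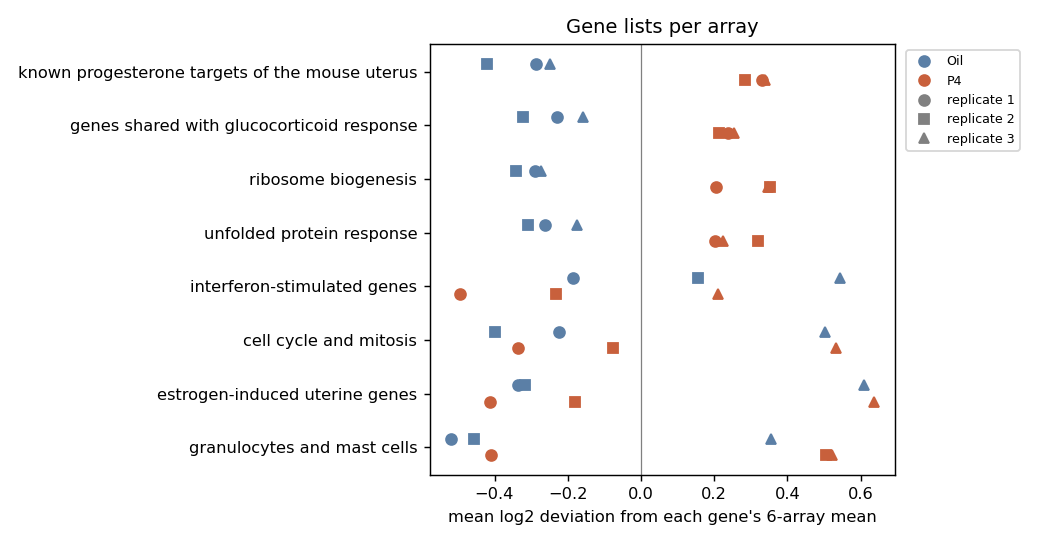
Mean log2 deviation of each list's genes from their own mean over 6 arrays (horizontal axis), per array; blue points are oil, orange points P4, and symbols the replicate numbers. The ribosome biogenesis list lies between -0.34 and -0.27 on oil arrays and between 0.20 and 0.35 on P4 arrays, while cell cycle and estrogen-induced genes are highest on the replicate 3 array of each group.

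Signalling genes changed in both directions within most lists. None of these 8 lists passed camera as a whole, while directional fry called the EGF family (adjusted p 0.0319) and Wnt (0.0131) lists. By mixed fry all 8 passed, with adjusted p from 1.19e-05 for the Wnt and TGF-beta lists to 0.000441 for GATA factors. In the hedgehog list 3 of 20 genes rose and 0 fell (4 and 0 adjusted over the list alone, and 4 and 0 by limma at an unadjusted p under 0.05; 5 and 0 with the replicate block): Ihh, Gas1 and Gli3. In the EGF family list, which also holds the inhibitor Errfi1, Errfi1 and Egfr rose (Egfr 0.87 ± 0.11) and Erbb3 was lower. The counts were 2 and 1 of 15, with 2 and 2 adjusted over the list alone and 4 and 2 with the block. In the FGF family list, which also holds Hand2, Spry1 and Etv5 from outside the family, Fgf1 and Hand2 were higher. Fgf18 (-1.23 ± 0.21), Spry1, Fgfr2 and Etv5 were lower. The counts were 2 and 4 of 21, with 2 and 5 adjusted over the list alone and 2 and 1 with scaling to the hybridisation controls. In the Wnt list the receptors Fzd1 (0.85 ± 0.09) and Fzd6 (0.79 ± 0.11) rose, and Wnt7a, Lgr5, Rspo3, Wnt5b and Rspo1 were lower, 2 and 5 of 35 (2 and 13 adjusted over the list alone; 3 and 13 with the block). TGF-beta and BMP genes had 3 higher and 7 lower of 34 (5 and 7 adjusted over the list alone; 6 and 8 with the block), a balance that turned to 5 and 2 with scaling to the hybridisation controls and was 1 and 1 without oil replicate 2 and 0 and 2 without P4 replicate 2. Hoxa11 (0.90 ± 0.08), Hoxa10 (0.81 ± 0.10) and Hoxa9 were higher and Meis2 (-0.59 ± 0.08) and Meis1 lower, 3 and 2 of 25 homeobox genes (3 and 3 adjusted over the list alone). Gata2 was higher and its partner Ldb1 lower among 12 GATA factors and partners (1 and 1 adjusted over the list alone; 2 and 2 with the block). Among 23 steroid receptors and cofactors 3 were higher and 5 lower, and 3 and 6 adjusted over the list alone. The counts were 3 and 3 with scaling to the hybridisation controls or without oil replicate 1 or 2. The higher genes were Fkbp5, Hsp90aa1 and Hsd11b2, none of them a receptor. The lower genes were the receptors Pgr, Esr1, Nr3c1 (glucocorticoid receptor, -0.52 ± 0.08) and Nr3c2 (mineralocorticoid receptor, -0.59 ± 0.08) and the cofactor Ncoa2. Camera adjusted p ranged from 0.122 for the Wnt list to 0.945 for GATA factors. Rspo3, Wnt5b, Etv5, Hoxa9, Hsp90aa1, Nr3c1 and Ncoa2 were named after their values were seen. Over these 8 lists 44 of 184 genes were called, but 23 without oil replicate 2 and 29 without P4 replicate 2. Gas1, Erbb3, Etv5, Fgfr2, Spry1, Lgr5, Rspo1, Hoxa9, Ldb1, Hand2, Esr1, Hsp90aa1 and Ncoa2 each lost their call without at least 1 array (adjusted p up to 0.17). Gli3 lost its call whichever array was left out (up to 0.127) and with the mean of all its probe sets (0.206). Meis2 lost its call without cross-hybridising probe sets (0.0799) and Meis1 with the mean of all its probe sets (0.061). With scaling to the hybridisation controls Spry1, Fgfr2, Ldb1, Rspo1 and Esr1 lost theirs (up to 0.112).

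Clock genes and retinoid enzymes were split in the same way. Of 20 clock genes 3 rose and 5 fell (5 and 7 adjusted over the list alone; 4 and 8 with the replicate block; 5 and 4 with scaling to the hybridisation controls). Nfil3 rose from 202 ± 31 to 718 ± 80 (1.75 ± 0.13) and Npas2 by 1.59 ± 0.21, while Rora (-1.01 ± 0.11) and Per3 (-0.93 ± 0.13) were lower. Of the 9 probe sets of Rora, 1 had the opposite sign at an unadjusted limma p under 0.05. Of 23 retinoid genes Cyp26a1 and Aldh1a2 were higher and Aldh1a3 (-1.41 ± 0.18) and Cyp26b1 lower (2 and 3 adjusted over the list alone; 6 and 4 with the block; 3 and 1 with the scaling). Of 21 prostaglandin genes Ptger3, a receptor for prostaglandin E2 (1.49 ± 0.14), Alox12 and Ptges2 were higher and Hpgd lower (4 and 2 adjusted over the list alone; 4 and 2 with the block). Of 20 cholesterol synthesis genes Dhcr7 was higher (0.73 ± 0.09) and Stard4 and Fdft1 lower (2 and 3 adjusted over the list alone; 5 and 3 with the block; 3 and 1 with the scaling). Among 24 ion and water transport genes Sgk1, the sodium pump subunit Atp1b1 (1.99 ± 0.15) and Slc26a6 were higher and Fxyd3 and Aqp1 lower (4 and 2 adjusted over the list alone; 5 and 2 with the block; 5 and 1 with the scaling). Among 30 matrix remodelling genes Adamts9, Adamts1 and Adamts15 were higher and Mmp11 (-1.19 ± 0.15) and Adamts5 lower (4 and 2 adjusted over the list alone; 6 and 6 with the block; 4 and 1 with the scaling). None of these 6 lists passed camera or directional fry as a whole, with camera adjusted p from 0.211 for transport to 0.901 for retinoid genes. By mixed fry all 6 passed, with adjusted p from 5.68e-05 for clock genes to 0.00773 for matrix genes. Slc26a6 and Adamts5 were named after their values were seen. Over the 6 lists 29 of 138 genes were called, but 17 without oil replicate 2 and 18 without oil replicate 1. Aldh1a2, Cyp26b1, Alox12, Ptges2, Stard4, Fdft1, Slc26a6, Fxyd3, Aqp1, Adamts9, Adamts15 and Adamts5 each lost their call without at least 1 array (adjusted p up to 0.164), as did Hpgd without cross-hybridising probe sets (0.549) and Cyp26b1, Fdft1 and Aqp1 with scaling to the hybridisation controls (up to 0.106).

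Estrogen-induced genes did not shift in 1 direction as a list. Igf1 rose from 1441 ± 68.6 to 5595 ± 1430 (1.91 ± 0.18), Greb1 by 1.42 ± 0.12 and Ctsd also rose, while Wnt7a, Padi1 (-1.18 ± 0.17), Pgr, Inhbb and Ccnd1 were lower, 3 and 5 of 27 (3 and 5 adjusted over the list alone; 3 and 3 with scaling to the hybridisation controls; camera adjusted p 0.944). Ccnd1 was also the 1 called gene of 33 cell cycle genes (0 adjusted over the list alone; 2 higher and 4 lower with the block; camera adjusted p 0.843), a list in which Pcna had 1781 ± 244 after oil and 2032 ± 287 after P4. Among 38 chemokines and cytokines Il6 (1.27 ± 0.17) and Ccl25 were higher and Tnfsf10 (-1.29 ± 0.16) and Cxcl17 lower (2 and 2 adjusted over the list alone; 4 and 3 with the block; camera adjusted p 0.782). Immediate early and stress genes had 5 higher and 3 lower of 34 (8 and 4 adjusted over the list alone; 9 and 5 with the block; camera adjusted p 0.122), but 0 and 1 without oil replicate 2 and 0 and 2 without P4 replicate 2. Interferon-stimulated genes passed camera as lower after P4 (adjusted p 0.0169, mean log2 difference -0.34) but not with an estimated correlation (adjusted p = 0.96), and 1 of 27 members was called, Xaf1 (-0.81 ± 0.20), with 0 adjusted over the list alone and 8 lower at an unadjusted p under 0.05. With the replicate block 14 members were lower and camera gave 1.1e-05, beside 0.506 with an estimated correlation. The list missed the threshold without oil replicate 3 (0.324) and without P4 replicate 1 (0.195). By mixed fry the estrogen-induced (adjusted p 5.68e-05) and the immediate early and stress (0.000377) lists passed. The chemokine (0.0807), interferon (0.267) and cell cycle (0.542) lists did not. Without oil replicate 2 the calls over these 5 lists went from 21 to 8 of 158 genes. Ctsd (named after its value was seen), Ccnd1, Cxcl17 and Xaf1 each lost their call without at least 1 array (adjusted p up to 0.145). Inhbb and Ccl25 lost theirs whichever array was left out (up to 0.132). With scaling to the hybridisation controls Ccnd1 (0.202) and Inhbb (0.0688) also lost theirs. Cell cycle, estrogen-induced, interferon and chemokine genes were highest on the replicate 3 array of each group.

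Markers of the cell types of the uterus were mostly uncalled between P4 and oil. In the epithelial list the tight junction gene Cldn3 rose from 1870 ± 185 to 4376 ± 645 (1.21 ± 0.12), Sox17 and Ehf were higher and Wnt7a and Dsp lower, 3 and 2 of 28 (3 and 6 adjusted over the list alone; 4 and 9 with the replicate block; 4 and 1 with scaling to the hybridisation controls). In the stromal list Hoxa11, Hand2 and Twist2 were higher and Lum lower, 3 and 1 of 25 (3 and 1 adjusted over the list alone; 6 and 2 with the block). In the endothelial list Cldn5 (-0.92 ± 0.16), Sox7 (-0.88 ± 0.16) and Tek were lower, 3 of 26 (3 adjusted over the list alone; 1 higher and 6 lower with the block; 1 and 2 with the scaling), with a camera adjusted p of 0.0662 that became 0.0228 with the block; with an estimated correlation these were 0.96 and 0.868. In the smooth muscle list Pgm5, Pln and Pcp4 were lower, 3 of 23 (3 adjusted over the list alone), and in the adipocyte list Scd1 and Lipe, 2 of 16 (5 adjusted over the list alone; 1 higher and 7 lower with the block). Rspo1 was the 1 call of 12 mesothelial genes (1 adjusted over the list alone; 2 with the block). Hdc was the 1 call of 20 granulocyte and mast cell genes (1 adjusted over the list alone). The neutrophil genes S100a8 and S100a9 varied within groups and did not pass, with S100a8 at 1028 ± 1660 after oil and 2779 ± 2460 after P4. By limma 0 of 26 macrophage genes (2 higher with the block), 0 of 22 lymphocyte genes (1 lower with the block) and 0 of 6 red blood cell genes were called, also adjusted over the list alone; at an unadjusted p under 0.05 there were 0, 1 and 0. Camera adjusted p of these 10 lists ran from 0.0662 to 0.868. By mixed fry the epithelial (adjusted p 0.000112), stromal (0.000174), endothelial (0.0151), adipocyte (0.0198), smooth muscle (0.0276) and mesothelial (0.0344) lists passed. The granulocyte (0.542), lymphocyte (0.633), red blood cell (0.645) and macrophage (0.795) lists did not. Over the 10 lists 19 of 202 genes were called, but 7 without oil replicate 2 and 10 without oil replicate 1. Ehf (named after its value was seen), Dsp, Twist2, Lum, Tek, Pgm5, Pln, Pcp4, Scd1 and Rspo1 each lost their call without at least 1 array (adjusted p up to 0.151). Lipe lost its call whichever array was left out (up to 0.17). Dsp, Tek, Pgm5, Pln, Pcp4, Scd1, Lipe and Rspo1 also lost theirs with scaling to the hybridisation controls (adjusted p up to 0.185).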

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

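The probe sets without a single gene name were examined only after the comparison of P4 with oil had been seen. When all 45037 probe sets other than controls were tested together, 171 of the 10092 without a single gene name were higher and 376 were lower after P4 at a limma adjusted p under 0.05, a signal in data that the gene comparison leaves out. Over all 45037 probe sets the same test called 1859 higher and 2022 lower, a larger share. The largest increase among those without a single gene name was 3.25 on the log2 scale. No explanation was tested.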

How the results depend on the processing

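The tests with scaling to the hybridisation controls, the covariates, arrays left out by number and the blocked fit with a covariate or an estimated correlation were chosen only after the results were seen. The main counts were 2368 genes (1106 higher, 1262 lower) and 5 lists. With the replicate block, which pairs the arrays by number, they were 3801 (1690, 2111) and 6, the addition being the endothelial list; Mcm7, Lmo2, Zfpm1, Thy1, Car3 and Krt19, not called in the main fit, were called, and it changed no other call of a named gene. With 1 array left out the counts ran from 990 to 2299 (higher 483 to 1071, lower 507 to 1228), and the lists from 5 to 8. All probe sets gave 3881 (1859, 2022), a 1.5-fold minimum 969 (486, 483), an adjusted p under 0.01 881 (440, 441) and one under 0.1 3528 (1607, 1921). Scaling to the hybridisation controls gave 2551 (1927, 624). Leaving out both arrays numbered 1 gave 1059 (545, 514), numbered 2 171 (99, 72) with 8 lists, and numbered 3 1453 (756, 697); of the 110 named genes called, 31, 73 and 25 lost their call without those numbered 1, 2 and 3, 13 to 40 with 1 array left out, 24 with the 1.5-fold minimum, 17 with scaling to the controls, 15 with the mean of a gene's probe sets and at most 6 in each other fit. The block with the 3' to 5' ratio gave 3738 (1736, 2002) and 13 lists. An estimated correlation left 0 lists, with or without the block (3 lists each had an unadjusted camera p under 0.05, and fry called 6). Its adjusted p was 0.45 for progesterone, glucocorticoid, unfolded protein and ribosome lists and 0.96 for interferon genes; with the block it was 0.506 for progesterone, glucocorticoid and interferon genes and 0.806 for the other two. The interferon list also missed the threshold without the dimmest 30% (0.0541) or 50% (0.117) of genes, by fry (0.501) and with the 3' to 5' ratio (0.0547); the progesterone list did with scaling to the controls (0.0568). With 1 array left out the adjusted p ran from 5.97e-05 to 0.00727 for the progesterone list, 0.000172 to 0.00592 for the glucocorticoid list, 2.73e-05 to 0.324 for interferon genes, 1.18e-11 to 6.11e-09 for the unfolded protein response and 3.07e-21 to 4.01e-18 for ribosome biogenesis. With the granulocyte mean as a covariate, the macrophage list turned to lower after P4 (adjusted p 0.000161) and S100a9 to -0.76. The cause of these changes was not tested. The other alternatives kept the gene count within 1.5 times, and the signal of dim genes over background limits what can be called among them.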

Other observations

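The tests of replicate 3 by RNA quality and by cell division were chosen only after the result was seen; the lists of tRNA synthetases, FoxO targets, the amino acid response, glycolysis, multiciliated cells and ribosomal proteins were drawn up after the leading genes had been seen, and before their own values were.

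Of 19 cytosolic tRNA synthetases, which attach amino acids to their tRNAs, 11 rose after P4 and 0 fell (14 and 1 at an unadjusted p under 0.05 by limma), among them Aars (1.03 ± 0.10), Gars (0.99 ± 0.08) and Iars (0.80 ± 0.11). Of 21 enzymes, transporters and stress regulators of the amino acid response other than those seen first, 7 rose, Sesn2 and the enzymes Mthfd1 (1.41 ± 0.10), Phgdh (1.20 ± 0.18), Aldh18a1, Shmt2, Got1 and Mthfd1l. Neither list passed camera with an estimated correlation (adjusted p 0.0926 for the synthetases and 0.21 for the others). These 7 were 3 without oil replicate 2 and 4 without oil replicate 1, and the 11 synthetases were 7 without either. Of 43 structural proteins of the ribosome 1 was called, Rpl12, at a mean log2 difference of 0.02 over the list.

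Of 32 targets of FoxO transcription factors outside the leading decreases 19 fell after P4 and 1, Sod2, rose, while Sgk1, a kinase that phosphorylates FoxO proteins, was among the largest increases. Klhl24 had a log2 fold change of -1.23 ± 0.10, Sesn3 of -1.15 ± 0.08, the muscle atrophy ligase Fbxo32 of -1.06 ± 0.09 and the cell cycle inhibitor Cdkn1b of -0.58 ± 0.09. Their mean differed by -0.41, beside -0.29 with scaling to the hybridisation controls, where 15 fell and 2 rose.

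The rise of ribosome biogenesis genes, with a mean log2 difference of 0.60, was set against RNA quality and leukocyte content differing between arrays. With the 3' to 5' ratio of control transcripts in the model the mean was 0.622 with a standard error of 0.043. With the granulocyte mean in the model it was 0.558 with one of 0.036. So neither measure, as a covariate, took up most of the difference. The ratio differed little between the groups (P4 minus oil 0.099 log2, exact permutation p 0.7), so it had little to take up. The granulocyte list holds Hdc, itself called higher, and 6 arrays allow only a coarse adjustment. Other differences in RNA quality or leukocyte content stay open as a cause of the rise of this list. The tRNA synthetases, which a wider rise of the machinery of protein synthesis predicts to go up, did so (camera p 1.13e-10 with a preset correlation). With an estimated correlation camera gave p = 0.0309, adjusted 0.0926 over 6 lists. With 1 array left out the estimated p ran from 0.01 to 0.0686, under 0.05 in 3 of 6 fits. A wider rise may thus account for part of the rise of ribosome biogenesis genes as a hypothesis. The amino acid response tested below was not told apart from a wider rise of this machinery. Structural ribosomal proteins, the core of that machinery, go against it with a mean of 0.02 ± 0.02 (SE over 43 genes, camera p 0.835), although only 10 other genes reach their median intensity of 13000, where the array may respond less, so a rise of the whole machinery is not shown. The lower hybridisation controls on P4 arrays stay open as to the level of all genes; scaling to them moves all genes nearly alike and so decides nothing about this list against others.

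The replicate 3 array of each group shared a pattern: 135 genes were at least 2-fold above the mean of the other replicates in both groups and 0 at least 2-fold below, a comparison with no limma or other test. Cxcl5 (6.57 log2 in oil, 5.76 in P4), Sprr2f (5.41, 4.87), Ltf (4.01, 4.07) and S100a9 (5.44, 3.47) were among the highest. RNA quality differing between arrays is argued against, since the 3' to 5' ratio of replicate 3 lay outside the range of the others on the same side in 0 groups. Leukocyte content alone cannot be told apart, because estrogen-induced genes other than Ltf and Lcn2 had a median excess of 0.324 in P4 and 0.335 in oil. Their members went both ways, with standard errors over genes of 0.37 and 0.313. The granulocyte and mast cell list had median excesses of 0.178 in P4 and 0.135 in oil, with standard errors over genes of 0.316 and 0.454. Its mean deviation was 0.506 on P4 replicate 2 and 0.523 on P4 replicate 3, but -0.455 on oil replicate 2 and 0.355 on oil replicate 3. The macrophage list was highest on replicate 3 of each group. Its mean deviations on replicates 1 to 3 were -0.586, -0.084 and 0.526 in oil and -0.806, 0.392 and 0.557 in P4. Cell cycle genes had median excesses of 0.611 ± 0.15 in oil and 0.66 ± 0.119 in P4. These errors are over 33 genes on 1 array per group and ignore the correlation of the genes (estimated 0.652). A dividing state of these uteri is a candidate explanation, while the estrogen-induced genes above leave an estrogen-exposed one undecided. Interferon-stimulated genes also had median excesses, 0.442 ± 0.083 in oil and 0.492 ± 0.104 in P4, which were not set against any explanation. A shared day or batch, which the labels do not give, stays open as untested.

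Pik3ip1 among the largest decreases led to the hypothesis that FoxO activity may be lower after P4. The targets outside the leading decreases were lower than other genes (camera p 4.66e-11 with a preset correlation; p = 0.00166 with an estimated correlation, adjusted 0.00996 over 6 lists), with the same direction and an estimated p of at most 0.00633 when any 1 array was left out. Of the 32 genes 6 stand in lists tested earlier; without them 15 of 26 fell and 1 rose (estimated p 0.00194). FoxO protein was not measured, many of these genes also answer to other regulators of growth and stress, and no technical explanation was tested, so the hypothesis stays open.

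Mthfd2 and Asns among the increases led to a test of an ATF4-type amino acid response: the other genes gave a camera p of 0.000125 (p = 0.105 with an estimated correlation). Atf4 itself (0.78 ± 0.07) and Sesn2 (0.43 ± 0.11) rose, while Ddit3 (-0.23 ± 0.15), Trib3 (-0.10 ± 0.18) and Chac1 (-0.08 ± 0.11), like Sesn2 members of that list, did not pass; these 5 were picked out after their values were seen, and the response stays open. Pfkfb3 and Slc2a3 led to a test of higher glycolytic gene expression, which the other glycolysis genes left undecided (camera p 0.613, 1 higher and 1 lower of 17). Capsl led to a test of multiciliated cell genes, also undecided (camera p 0.292, mean -0.07, 0.05 with scaling to the hybridisation controls, 1 lower of 27).

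Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many changed genes as P4 against oil, the real one, with 2368 genes against 8 in the highest other split. For the lists 8 of the 10 splits called as many as the real 5, and the highest other called 17. The share cannot fall under 0.1 with 10 splits, which is too few to decide. Splits that part all 3 pairs, like the real one, called 3 to 5 lists, and the others, which part 1 pair, called 7 to 17, so the list test with a preset correlation follows the structure shared by arrays of 1 number.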
